A study of Mus musculus with 6 samples.

How the data were processed

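The 6 libraries hold total RNA of germinal vesicle oocytes, 3 from Ring1-null, Rnf2-floxed females with Zp3-cre (dKO) and 3 from females without it (control). Per the labels' protocols, granulosa cells were stripped from the oocytes by pipetting, 15 oocytes of 1 female were pooled, and the RNA was amplified with the Ovation v2 kit before TruSeq library preparation and HiSeq sequencing. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, with 1 column per library. Per the submitters' processing notes TopHat2 2.0.11, Cufflinks 2.0.2 and build mm9 were used. Their roles, the gene annotation, the use of strand and any scaling between libraries are not given in the sources used here. Without stated strand, reads of overlapping genes cannot be told apart, and reads of near-identical copies may be split between them. Of the 114 named genes 35 have exons that overlap another annotated gene, so their values are uncertain to that extent.

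The table has 24525 rows. Of these, 497 repeated a symbol and all its values and were removed, which left 24028 genes, 3718 of them at 0 in all libraries. The sums of FPKM were 318273, 318471 and 327480 in controls 1 to 3 and 278701, 309549 and 278838 in dKO libraries 1 to 3. Absolute depth is unknown, so no counting interval is given. Relative depth was read from the commonest ratio among low values of the same gene in different libraries, on the assumption that values are whole multiples of 1 fragment. It was lowest in dKO replicates 1 and 2, at 0.661 and 0.805 of control replicate 1, so low values are less precise there. Pearson correlations of log2(FPKM + 1) were 0.982 to 0.983 within controls, 0.928 to 0.948 within dKO libraries and 0.866 to 0.917 between groups. The leading principal component held 65.5% of the variance and parted the groups, and the next held 15.4% and parted dKO replicates 1 and 3.

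Genes with at least 1 FPKM in at least 3 libraries were kept, which left 11334, including 36 of 1183 small RNA genes. A pseudocount of 1 was added, and limma 3.58.1 in R 4.3.3 was fitted to the log2 values (lmFit and eBayes with trend, two-sided). The p-values were adjusted by the Benjamini-Hochberg method over all kept genes, with a threshold of 0.05. Ring1 was below the filter and was fitted with the kept genes added to it. Fold changes are on the log2(FPKM + 1) scale and understate those of low genes. Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 of 25 lists with at least 5 kept members (all 25 with no filter on low values), and again with an estimated correlation and with fry. Of the 11 lists called at the preset correlation (9 higher, 2 lower), 4 held with an estimated correlation: Hox genes, other homeobox genes, non-homeobox factors and H3K27me3-dependent imprinted genes. Among those that did not hold, the signalling, granulosa and neuronal lists had estimated correlations of -0.0177, -0.0476 and -0.0587, below the preset one. A higher correlation among members therefore does not account for the loss of these calls, and its cause was not tested. The number of detected genes was compared by an exact permutation test.

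The samples, tests, gene lists and rule for named genes were fixed before the data were examined. The rule takes Ring1 and Rnf2, the 12 largest rises and 12 largest falls past the threshold with no overlap between groups, and up to 3 rising and 3 falling members of each list past the threshold. Where no member passes, it takes up to 2 of the highest mean, and from lists of other cell types also the 2 of the highest mean. Symbols of predicted genes (Gm or LOC numbers, Rik) and symbols on more than 1 row were left out of the largest changes. The values of some genes that the rule takes are not reported here. Some genes stand on more than 1 list, so the lists are not independent.

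Per the labels, libraries with the same replicate number shared a flow-cell lane, so the number marks a shared lane and pairs libraries across the groups. The deviations of same-numbered libraries from their group means correlated at 0.147, 0.107 and 0.0637 for replicates 1, 2 and 3. The tests reported were unpaired, with no block in the fit, and a fit with the replicate number as a block was an alternative. All dKO libraries carried one index sequence and all controls another, so index and group cannot be told apart.

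The alternatives planned were other pseudocounts, filters, scalings, variance models, thresholds, the block and the removal of each library. Added after seeing the data were the removal of small RNA genes, a correction for GC content and transcript length, lists without shared members and the centring of each library on its mean. The GC and length correction removed a smooth surface (loess, span 0.5) from each library's deviations from the gene means. It was first run with a least-squares smoother, which made falls outnumber rises, and then with a robust one that follows the bulk of genes. The robust smoother was chosen after the least-squares result was seen, and both are reported. Transcript properties and gene order came from GENCODE M21 on GRCm38, another build than that of the deposited values, so no coordinates are given. Of the kept genes 99.3% had a transcript sequence and 99.6% a place in the gene order.

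The fit was tested on simulated data with the spread of the 11334 kept genes in the comparison of dKO with control. With 200 genes changed, 44% of those changed by 1 log2 unit and 88% of those changed by 2 were recovered, with 5 calls outside the changed genes. With 2000 genes changed, 75.9% and 97.5% were recovered and 5.13% of the calls were false. Camera called 0 lists with no change and 1 when the Hox list was shifted. The simulated genes were drawn independently, with the same spread in both groups. Lists with correlated members were therefore not covered, and the oocyte list had an estimated correlation of 0.247. The larger spread of the dKO libraries was not covered either. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, permutations and figures.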

Results

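RNA was measured in fully grown mouse oocytes at the germinal vesicle stage, the arrested stage before meiotic maturation. The design asks which transcripts differ when oocytes that lack Ring1 also lose Rnf2. Both encode E3 ubiquitin ligases that form the catalytic core of Polycomb repressive complex 1 (PRC1). Both groups came from Ring1-null females with floxed Rnf2 alleles on a mixed strain background. The 3 dKO libraries also carried Zp3-cre, a recombinase transgene active in growing oocytes, and the 3 control libraries did not. An effect of the transgene itself therefore cannot be told apart from the loss of Rnf2. Each library was made from 15 oocytes of 1 female of about 3 months, so the replicates were separate animals. The values are FPKM, which keep no absolute depth. Relative to control replicate 1, the depth recovered from low values was 0.903 and 1.02 in the other controls and 0.661, 0.805 and 1.08 in dKO replicates 1 to 3, so the lowest depths were in the dKO group.

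Rnf2 RNA fell in all 3 dKO libraries. Its level was 49.6 ± 3.62 FPKM in controls (SD, n = 3) and 9.51 ± 4.82 FPKM in dKO oocytes (SD, n = 3), which is 19.2% of the control mean. The dKO libraries held 14.8, 8.44 and 5.31 FPKM, and the lowest control held 46.8 FPKM. The log2 change was -2.37 ± 0.30 (SE; limma adjusted p = 0.000696). Ring1, deleted in both groups, was at 0.0498 ± 0.0420 FPKM in controls and 0.121 ± 0.113 FPKM in dKO oocytes (SD, n = 3; limma adjusted p = 0.673). Rnf2 followed the genotype labels. Ring1 was near 0 in both groups, but no library with intact Ring1 was measured, so its level cannot check the labels. The deleted exons are not given in the sources used here, and Rnf2 exons overlap Trmt1l on the other strand, so the remaining Rnf2 signal cannot be assigned to intact alleles.

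Between dKO and control oocytes, both Ring1-null, 2385 of 11334 genes differed, with 1587 higher and 798 lower in dKO oocytes (limma, Benjamini-Hochberg adjusted). The rises were larger: 1097 genes rose and 269 fell by at least 1 log2 unit, and 301 rose and 14 fell by at least 2. Plod2, a collagen lysyl hydroxylase, went from 0.371 ± 0.0753 to 68.0 ± 3.82 FPKM, a log2 change of 5.65 ± 0.17 (SE; limma adjusted p = 1.77e-06). The metallothionein gene Mt1 went from 0.520 ± 0.392 to 73.5 ± 13.4 FPKM (SD, n = 3). Log2 changes of 4.26 to 4.85 were found for the growth factor Igf2, the placental gene Plac1, the homeobox gene Irx1, the fatty acid binding protein gene Fabp7, the keratin gene Krt79, Stambpl1, Prrg3 and the connexin gene Gjb2. Changes are on the log2(FPKM + 1) scale, which understates those of genes with low values.

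Among the falls, Cpne9 dropped from 27.4 ± 0.785 to 3.80 ± 3.20 FPKM, Vwa3a from 10.3 ± 0.754 to 1.09 ± 0.218 FPKM and the claudin gene Cldn15 from 9.94 ± 2.84 to 1.20 ± 0.117 FPKM (SD, n = 3). Vmn1r112, Ceacam2 and Klhdc1 had log2 changes of -2.19, -1.99 and -1.90 (limma). Atp6v0c, a subunit of the vacuolar proton pump, stood at 16.4, 36.4 and 11.8 FPKM in controls and at 6.04, 5.54 and 0.00031 FPKM in dKO oocytes. The immune receptor gene Btla stood at 13.4, 11.2 and 11.4 FPKM in controls and at 0.835, 8.03 and 0.323 FPKM in dKO oocytes. Atp6v0c lost its call on removal of any 1 control and Btla on removal of any 1 library except dKO replicate 2, with limma adjusted p up to 0.120 and 0.109. On all libraries Atp6v0c also lost it with pseudocounts of 0.1 (0.0957) and 0.5 (0.0529). Snora62 and Snora74a were listed at 0 in every dKO library, against 18.6, 13.7 and 12.1 FPKM and 2.38, 1.32 and 9.32 FPKM in controls, and Mir8108 averaged 48.3 ± 9.69 FPKM in controls and 0.549 ± 0.951 FPKM in dKO oocytes (SD, n = 3). Snora74a lost its call with array weights (limma adjusted p = 0.0736). These last 3 are very short RNA genes, for which a value near 0 can be a failed estimate.

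**Figure D1:**
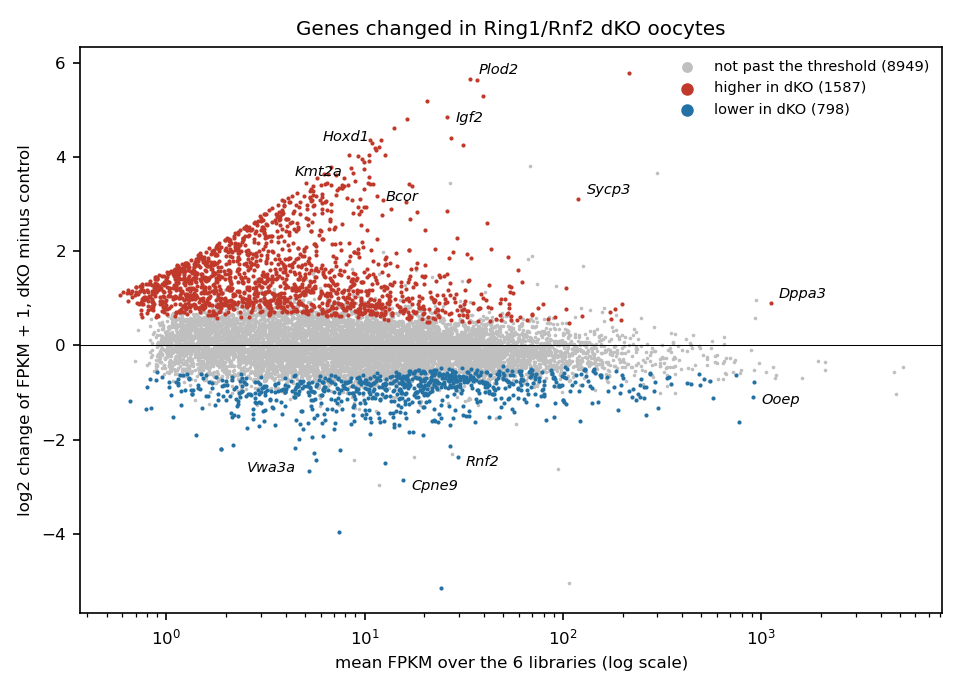
Log2 change of FPKM + 1 (dKO minus control, 3 libraries each) against mean FPKM over the 6 libraries on a log axis, with each point 1 of the 11334 genes. The 1587 genes that rose (red) reach higher values than the 798 that fell (blue) and lie mostly at low mean FPKM, and genes past the threshold are coloured whether or not they are labelled.

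The split between rises and falls depended on where the libraries were centred. Rises made up 66.5% of the calls on the deposited scale and 63.6% after median-ratio scaling, but 52.6% after quantile normalization (1191 rose, 1073 fell), which also ended the calls of Eed, Tdrd1, Tdrkh, Klf5, Ooep, Inhba, Wee2, Fen1, Nsd1, Rps15 and Fdft1. With each library centred on its mean, which was added after seeing the data, falls outnumbered rises (1452 rose, 1572 fell, 48.0% rising, median of all genes -0.12). On the deposited scale that median was -0.019. With no filter, over 20310 genes, Atp6v0c, Btla, Dppa3, Fdft1, Fgf8, Gadd45b, Inhba, Mos, Ndufs7, Nelfa, Ooep, Pecam1, Pold2, Rbm44, Rpl15, Rps15, Snora74a, Tdrd1, Tgfb3, Tle6, Uqcr11, Wee2 and Zscan4c were not past the threshold (limma adjusted p 0.0505 to 0.145). Without dKO replicate 2 the calls were 1566 and 1465 (51.7% rising). Without control replicate 1, 2 or 3 the falls numbered 258, 262 and 231, against 1136, 1087 and 1101 rises. The 2 groups did not overlap at 41.5% of the genes, against 10% by chance. They also did not overlap at 1584 of the 1587 rising and all 798 falling genes, which the calls themselves nearly require. The dKO libraries varied more, with a median SD of 0.316 log2 units against 0.141 in controls.

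Genes that were silent or nearly so in control oocytes accounted for much of the rise. Of the rising genes, 785 (49.5%) had a control mean under 1 FPKM, and of the 1014 tested genes with such a mean 77.4% rose and 0 fell. The filter on 3 of 6 libraries keeps such genes mostly where the dKO values are higher. By mean FPKM over all libraries, 26.5% of genes in the lowest bin (under 3) rose and 3.73% fell, against 2.48% and 14.5% of genes over 100 FPKM. The lowest bin had 14.9% rising after quantile normalization. Genes at 1 FPKM or more numbered 10385 ± 137 in controls and 11486 ± 271 in dKO oocytes (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). The difference of 1100 genes became 1496 at 0.1 FPKM or more and 388 at 5 FPKM or more.

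Developmental transcription factors rose together in dKO oocytes. The filter keeps genes silent in controls mostly where dKO values are higher, so each count is over members that it favours. Of 39 Hox genes, which pattern the body axis, 12 were tested and all 12 rose (12 adjusted over the list alone; median log2 change 1.83; camera adjusted p = 5.03e-11). Hoxd1 reached 22.2 ± 8.72 FPKM from 0.210 ± 0.118, Hoxd9 19.97 ± 5.84 from 0.900 ± 0.292 and Hoxd13 31.4 ± 2.78 from 2.04 ± 0.390 (SD, n = 3). Of 105 other homeobox regulators 37 were tested, of which 25 rose and 2 fell (26 and 3 adjusted over the list alone; median 1.53; camera adjusted p = 1.25e-11), among them Irx1 and Irx2. Irx1 went from 0.141 ± 0.0228 to 28.2 ± 11.1 FPKM and Irx2 from 0.0288 ± 0.0135 to 13.6 ± 4.37 FPKM. The 2 that fell were Pax2, a kidney and eye regulator, at 19.7 ± 4.002 and 7.02 ± 2.92 FPKM, and Lbx1, a muscle precursor regulator, at 4.31 ± 0.742 and 1.17 ± 0.778 FPKM.

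Of 106 non-homeobox developmental factors 36 were tested, of which 26 rose and 1 fell (27 and 2 adjusted over the list alone; median 1.24; camera adjusted p = 1.25e-11). Ebf3 went from 1.04 ± 0.0380 to 20.9 ± 2.98 FPKM and Sall3 from 0.202 ± 0.104 to 9.75 ± 0.784 FPKM (SD, n = 3). The limb regulator Tbx4 fell from 107 ± 1.154 to 52.6 ± 17.8 FPKM, and lost its call without control replicate 3 (limma adjusted p = 0.0525). With no filter, among members above 0 in any library 17 of 37 Hox genes, 32 of 97 other homeobox genes and 39 of 97 non-homeobox factors rose and 0, 2 and 1 fell, with median log2 changes of 0.52, 0.44 and 0.49 (camera adjusted p = 2.55e-09, 5.56e-10 and 6.66e-11). With an estimated correlation the camera adjusted p was 0.0168 for the Hox list and 0.0125 for both other lists. In the same libraries 6 of 14 granulosa and cumulus markers rose, and Wt1 and Nr2f2 stand both among the developmental factors and among markers of other ovarian cells.

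**Figure D2:**
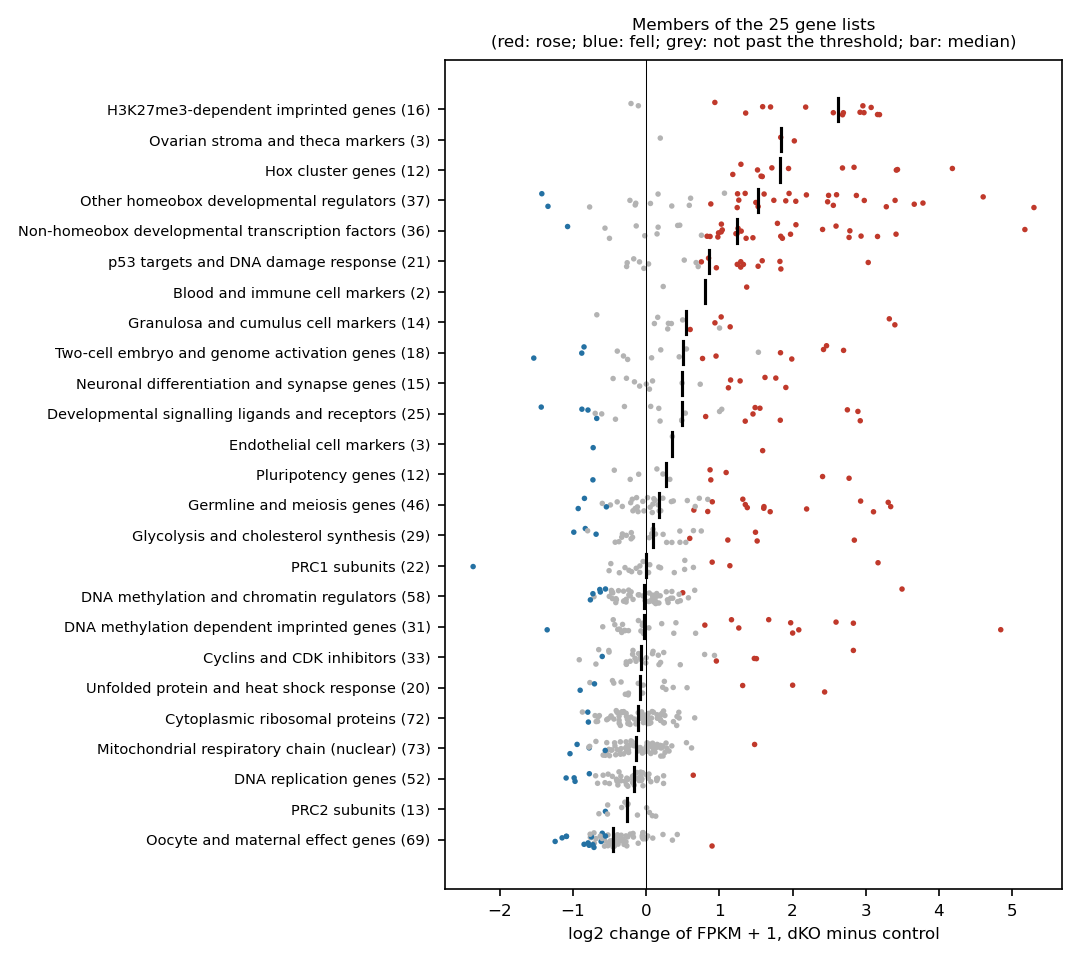
Log2 change of FPKM + 1 (dKO minus control, 3 libraries each) for the tested members of the 25 gene lists, with the number of members in parentheses, red for members that rose, blue for members that fell, grey for those not past the threshold and a black bar at the list median. All 12 tested Hox genes, of 39 on the list, lie to the right of 0, and the median of the 69 oocyte genes is -0.45.

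Signalling and neuronal lists were also higher. Of 84 developmental ligands and receptors 25 were tested, of which 9 rose and 4 fell (14 and 5 adjusted over the list alone; median 0.49; camera adjusted p = 0.0366, and adjusted p = 0.183 with an estimated correlation). With no filter 18 of 77 members above 0 in any library rose and 3 fell, with a median of 0.14 (camera adjusted p = 0.00357). The ephrin receptor gene Epha7 went from 1.32 ± 0.234 to 17.1 ± 5.32 FPKM, Fgf18 from 0.628 ± 0.176 to 11.6 ± 4.82 FPKM and Bmp2 from 0.00944 ± 0.00938 to 5.90 ± 1.52 FPKM (SD, n = 3). The falls were Fgf8 (log2 change -1.43), Tgfb2 (-0.88), Tgfb3 (-0.80) and the Notch ligand Jag1 (-0.68), the last named after its values were seen. Fgf8 lost its call without control replicate 2 or dKO replicate 1 (limma adjusted p up to 0.0627), and Tgfb3 on removal of any 1 control or dKO replicate 3 (up to 0.159) and with array weights (0.0522). The list itself was not past the threshold with the filter at 5 FPKM (camera adjusted p = 0.643), without dKO replicate 3 (0.0757), after the robust GC and length correction (0.0760, and 0.0670 with the replicate block), after quantile normalization (0.0537) or without members that another list holds (0.0511). Of 50 neuronal and synaptic genes 15 were tested, of which 6 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.49; camera adjusted p = 0.0152, and adjusted p = 0.158 with an estimated correlation). With no filter 12 of 47 members above 0 in any library rose and 0 fell, with a median of 0.22 (camera adjusted p = 0.000373). Gad2, which makes the transmitter GABA, the potassium channel gene Kcna1 and the netrin receptor gene Dcc had log2 changes of 1.91, 1.77 and 1.62, with dKO means of 5.38, 3.14 and 3.07 FPKM.

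Genes whose imprint depends on maternal H3K27me3, the mark set by Polycomb repressive complex 2 (PRC2), were higher as a group. Of 30 such genes 16 passed the filter, of which 14 rose and 0 fell (14 and 0 adjusted over the list alone; median log2 change 2.62; camera adjusted p = 2.25e-11, and adjusted p = 0.0125 with an estimated correlation). With no filter 17 of 26 members above 0 in any library rose and 0 fell (median 1.15; camera adjusted p = 1.68e-10). Rbms1 went from 0.646 ± 0.437 to 13.8 ± 2.26 FPKM, Sall3 from 0.202 ± 0.104 to 9.75 ± 0.784 FPKM and Clic6 from 0.00929 ± 0.00894 to 7.63 ± 1.73 FPKM (SD, n = 3). Of 31 genes imprinted through DNA methylation 10 rose and 1 fell (10 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.119, and adjusted p = 0.269 with an estimated correlation), while fry, which does not compare it with other genes, called it higher (adjusted p = 0.00120). Its median of -0.034 and mean of 0.57 differ in sign, and camera pointed upward. Igf2 went from 0.705 ± 0.0993 to 51.4 ± 24.8 FPKM, the CDK inhibitor gene Cdkn1c from 3.59 ± 0.583 to 33.1 ± 11.9 FPKM and Ascl2 from 0.0757 ± 0.0803 to 5.50 ± 0.368 FPKM. Snrpn fell from 8.16 ± 1.93 to 2.70 ± 1.36 FPKM, and was not past the threshold without control replicate 3 (limma adjusted p = 0.0591). Igf2, Cdkn1c and Snrpn overlap exons of other annotated genes.

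Genes of earlier germ cells rose in part. Of 46 germline and meiosis genes 14 rose and 3 fell (17 and 4 adjusted over the list alone; median log2 change 0.17; camera adjusted p = 0.0160, and adjusted p = 0.282 with an estimated correlation). Sycp3 and Syce1, components of the synaptonemal complex that joins chromosomes in meiotic prophase, went from 23.2 ± 0.829 to 216 ± 74.0 FPKM and from 1.01 ± 0.349 to 18.8 ± 1.47 FPKM (SD, n = 3). Sohlh1, a transcription factor of early oocyte growth, went from 0.234 ± 0.286 to 14.6 ± 10.04 FPKM. The 3 that fell act in the piRNA pathway: Tdrd1 (292 ± 24.6 to 160 ± 61.9 FPKM), Gtsf1 (252 ± 22.1 to 142 ± 30.6 FPKM) and Tdrkh (23.6 ± 0.690 to 15.9 ± 1.17 FPKM). Tdrd1 lost its call on removal of any 1 library except dKO replicate 3, Gtsf1 without control replicate 1 or 3 and Tdrkh on removal of any 1 control, with limma adjusted p up to 0.118, 0.0688 and 0.146. Tdrkh also lost it with the replicate number as a block (limma adjusted p = 0.0615). Without dKO replicate 1 the list had a camera adjusted p of 0.0522. Sycp3 exons overlap Chpt1 on the other strand.

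Camera called neither the pluripotency list nor the early embryo list on the deposited scale with all libraries and the filter. Of 20 pluripotency genes 12 were tested, of which 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0643, and adjusted p = 0.247 with an estimated correlation). The list was called higher by fry (adjusted p = 0.000936), with no filter (camera adjusted p = 0.0433) and after the robust and least-squares GC and length corrections (0.0465 and 0.0463). With the replicate block added, it was called after the least-squares correction (camera adjusted p = 0.0495) but not after the robust one. Klf4 went from 2.39 ± 0.327 to 22.2 ± 2.48 FPKM, Sox2 from 0.256 ± 0.104 to 6.00 ± 2.68 FPKM and Klf5 from 0.0992 ± 0.0495 to 1.35 ± 0.177 FPKM (SD, n = 3). Gbx2 and Tbx3, named after their values were seen, were the other 2, with log2 changes of 0.88 and 0.87. Of 18 genes of embryonic genome activation 7 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.166, and adjusted p = 0.618 with an estimated correlation). The rises were led by the heme oxygenase gene Hmox1 (log2 change 2.70) and by Zscan4f and Zscan4c (2.46 and 2.42), near-identical copies between which reads can be split. Rbm44, Klf17 and Nelfa had log2 changes of -1.54, -0.88 and -0.85. Rbm44 lost its call without control replicate 1 or dKO replicate 1, and Nelfa on removal of any 1 control or dKO replicate 1 (limma adjusted p up to 0.0579 and 0.0786).

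Oocyte and maternal effect genes were lower as a group. Of 69 members 1 rose and 14 fell (1 and 15 adjusted over the list alone), with a median log2 change of -0.45 (camera adjusted p = 2.99e-07, and adjusted p = 0.315 with an estimated correlation). Adjusted over all genes with no filter, 0 of the 69 rose and 5 fell (camera adjusted p = 6.66e-11). After quantile normalization the camera adjusted p was 0.0563. Of all tested genes with a mean over 100 FPKM 14.5% fell and 2.48% rose, and the list was not matched on expression. A fall of abundant transcripts in general was therefore not separated from a fall particular to this list. Mos, the kinase that holds mature eggs in arrest, went from 142 ± 4.54 to 64.5 ± 33.5 FPKM, and Tle6 and Ooep, parts of the subcortical maternal complex, from 316 ± 33.6 to 151 ± 64.5 FPKM and from 1211 ± 54.8 to 605 ± 250 FPKM (SD, n = 3). Dppa3, which protects the maternal genome from demethylation, was the 1 that rose, from 769 ± 159 to 1463 ± 435 FPKM (limma adjusted p = 0.0490). It was not past the threshold on removal of any 1 library except dKO replicate 2 (limma adjusted p up to 0.184), after median-ratio scaling (0.0597), mean centring (0.0772) or the least-squares GC and length correction (0.0551), with array weights (0.0639) or with the filter at 5 FPKM (0.0573). Mos and Ooep lost their calls on removal of any 1 control or dKO replicate 1, and Tle6 of any 1 control (limma adjusted p up to 0.0597, 0.115 and 0.0923).

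**Figure D3:**
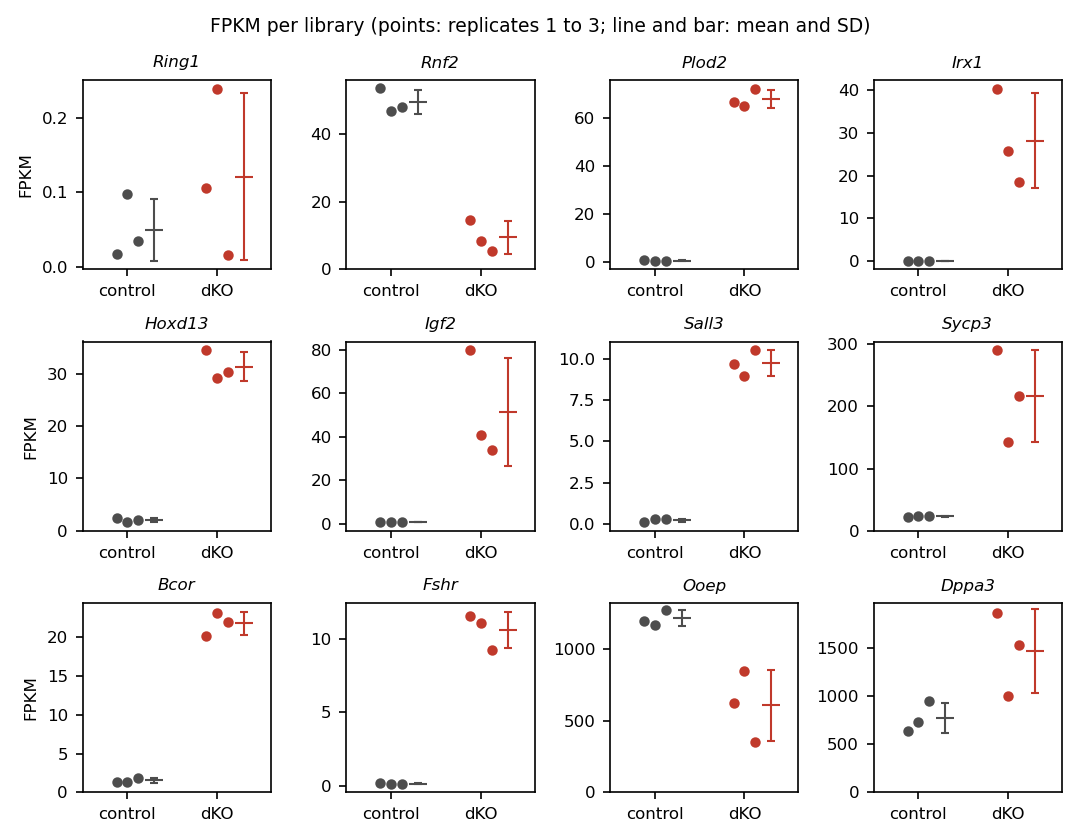
FPKM of 12 genes in each of the 3 control (grey) and 3 dKO (red) libraries, with the horizontal line and bar giving the group mean and SD and each panel on its own linear axis. Rnf2 lies at 46.8 FPKM or more in controls and at 14.8 FPKM or less in dKO oocytes, while Plod2 averages 0.371 and 68.0 FPKM.

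Most transcripts of the Polycomb complexes themselves were not past the threshold, as held for all tested genes, of which 14.0% rose and 7.04% fell. Of 22 PRC1 subunit genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.725, and adjusted p = 0.844 with an estimated correlation), and the median of -0.0044 and mean of 0.13 differ in sign, with camera pointing upward and fry calling the list higher (adjusted p = 0.0418). Bcor, a subunit of variant PRC1, went from 1.53 ± 0.282 to 21.7 ± 1.53 FPKM, Pcgf5 from 2.63 ± 0.0723 to 7.16 ± 1.80 FPKM and Phc3 from 7.81 ± 0.991 to 15.6 ± 3.32 FPKM (SD, n = 3). Rnf2 was the 1 that fell, and Phc3 lost its call without control replicate 2 or 3 (limma adjusted p up to 0.0779). Of 13 PRC2 subunit genes 0 rose and 1 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.0643, and adjusted p = 0.480 with an estimated correlation). The list was called lower with no filter (camera adjusted p = 0.0294), without control replicate 1 (0.0477) or dKO replicate 1 (0.0391) and after the robust and least-squares GC and length corrections (0.0337 and 0.0336). The gene that fell was Eed, at 45.9 ± 2.72 and 30.98 ± 3.34 FPKM, which lost its call on removal of any 1 control (limma adjusted p up to 0.138) and with the replicate block (0.0522).

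Of 58 genes for DNA methylation and chromatin regulators 2 rose and 5 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.372, and adjusted p = 0.691 with an estimated correlation). The H3K4 methyltransferase gene Kmt2a went from 0.619 ± 0.256 to 17.2 ± 2.05 FPKM, and the demethylase gene Kdm1a from 16.9 ± 1.145 to 24.3 ± 2.04 FPKM (SD, n = 3). The falls were Suv39h1 (log2 change -0.76), Dnmt3l (-0.73), Nsd1 (-0.63), Kdm6b (-0.63) and Dnmt3a (-0.56), the last 2 named after their values were seen. Suv39h1, Dnmt3l, Nsd1 and Kdm1a lost their calls on removal of any 1 control, with limma adjusted p up to 0.115, 0.0993, 0.123 and 0.203, and so did Suv39h1 and Kdm1a on removal of dKO replicate 1 and Kdm1a of dKO replicate 2. On all libraries Kdm1a, at a limma adjusted p of 0.0498, was not past the threshold with pseudocounts of 0.1 and 0.5 (0.0502 each), the filter at 5 FPKM (0.0585), eBayes without trend (0.0643) or robust (0.0537), mean centring (0.0813) or the replicate block (0.0866, and 0.0717 with the least-squares GC and length correction). Kmt2a and Dnmt3l exons overlap other genes on the opposite strand.

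The p53 target list was higher. Of 21 members 12 rose and 0 fell (13 and 0 adjusted over the list alone; median log2 change 0.85; camera adjusted p = 0.000205, and adjusted p = 0.220 with an estimated correlation). The cell death gene Pmaip1 went from 0.0762 ± 0.0740 to 8.33 ± 3.79 FPKM, Perp from 1.18 ± 0.226 to 6.73 ± 0.807 FPKM and Gadd45b from 1.12 ± 0.395 to 7.92 ± 6.15 FPKM (SD, n = 3). Gadd45b was not past the threshold on removal of any 1 control or dKO replicate 1 (limma adjusted p up to 0.0759). Of 20 genes of the unfolded protein and heat shock responses 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.862, and adjusted p = 0.911 with an estimated correlation). Hspb1, Asns and Bag3 had log2 changes of 2.44, 2.002 and 1.32, and Atf4 and Pdia4 of -0.90 and -0.71. Pdia4 lost its call on removal of any 1 control (limma adjusted p up to 0.0697). The median of -0.078 and camera pointed down while the mean of 0.14 and the fry test pointed up.

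DNA replication genes were called lower as a list at the preset correlation, and cell cycle genes were not called. Of 52 DNA replication genes 1 rose and 4 fell (0 and 1 adjusted over the list alone; median log2 change -0.17; camera adjusted p = 0.00876, and adjusted p = 0.392 with an estimated correlation). Over all tested genes 7.04% fell, a share near that of the list. The camera adjusted p was 0.114 after quantile normalization and 0.104 with the filter at 5 FPKM, and the fry adjusted p was 0.0764. The falls were the polymerase subunits Pold2 (log2 change -1.09), Pole2 (-0.98) and Pole (-0.97), and Cdc6 (-0.78), which was named after its values were seen. The flap endonuclease gene Fen1 was at 6.20 ± 0.652 and 10.3 ± 1.31 FPKM (SD, n = 3). Fen1, Pold2 and Pole lost their calls on removal of any 1 control (limma adjusted p up to 0.159, 0.127 and 0.0812), Fen1 and Pold2 also of dKO replicate 3, Pold2 of dKO replicate 1, and Fen1 with the replicate block (0.0507), array weights (0.0517) and mean centring (0.0764). Of 33 cyclin and CDK inhibitor genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.827, and adjusted p = 0.911 with an estimated correlation). Their median of -0.075 and camera pointed down, while the mean of 0.12 and fry pointed up. Cdkn1c, Cdk6 and Ccne1 rose by 2.83, 1.51 and 1.48 log2 units and Cdkn1a, named after its values were seen, by 0.96. Wee2, an oocyte kinase that maintains meiotic arrest, fell by 0.60 log2 units and lost its call on removal of any 1 control or dKO replicate 1 (limma adjusted p up to 0.162) and with the replicate block (0.0545).

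Camera called no housekeeping or metabolic list on the deposited scale with all libraries and the filter. Of 72 cytoplasmic ribosomal protein genes 0 rose and 2 fell (0 and 0 adjusted over the list alone; median -0.12; camera adjusted p = 0.0643, and adjusted p = 0.691 with an estimated correlation). The list was called lower with no filter (camera adjusted p = 0.00621), without control replicate 2 (0.0165), dKO replicate 1 (0.0268) or dKO replicate 2 (0.0429) and with each library centred on its mean (0.0467). The genes that fell were Rps15 and Rpl15, at log2 changes of -0.80 and -0.79, and both lost the call on removal of any 1 control or dKO replicate 3, Rps15 also of dKO replicate 1 and Rpl15 of dKO replicate 2 (limma adjusted p up to 0.167 and 0.176). On all libraries both lost it with the filter at 5 FPKM (0.0585 and 0.0552), and Rps15 with a pseudocount of 0.1 (0.0504), eBayes without trend (0.0612) and array weights (0.0604). Of 73 nuclear genes of the respiratory chain 1 rose and 4 fell (1 and 0 adjusted over the list alone; median -0.14; camera adjusted p = 0.0643, and adjusted p = 0.691 with an estimated correlation). This list was called lower with no filter (camera adjusted p = 0.00598) and without control replicate 2 (0.0120) or dKO replicate 1 (0.0268). Atp5g3, an ATP synthase subunit gene beside the Hoxd cluster, went from 9.79 ± 1.399 to 29.3 ± 4.97 FPKM (SD, n = 3), while Ndufs7, Ndufb2, Uqcr11 and, named after its values were seen, Ndufb3 fell by 1.04, 0.94, 0.78 and 0.56 log2 units. Ndufs7, Ndufb2 and Uqcr11 each lost the call without control replicate 2 or 3, and Ndufs7 and Uqcr11 also without control replicate 1 or dKO replicate 1 or 3 (limma adjusted p up to 0.0955, 0.0666 and 0.114). Of 29 genes of glycolysis and cholesterol synthesis 5 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.570, and adjusted p = 0.869 with an estimated correlation). The lactate dehydrogenase gene Ldha went from 0.885 ± 0.548 to 12.7 ± 4.90 FPKM and Cyp51 from 1.37 ± 0.0704 to 5.77 ± 0.276 FPKM, and Hk2 and Pgk1, named after their values were seen, rose by 1.12 and 0.60 log2 units. Pfkm, Pkm and Fdft1 fell by 0.99, 0.83 and 0.68, of which Pkm and Fdft1 lost the call without control replicate 2 or 3 and Fdft1 without control or dKO replicate 1 (limma adjusted p up to 0.0826 and 0.117).

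Markers of other ovarian cells were mostly low and rose in part. Of 32 granulosa and cumulus markers 14 were tested, of which 6 rose and 0 fell (7 and 1 adjusted over the list alone; median log2 change 0.55; camera adjusted p = 0.00158, and adjusted p = 0.0917 with an estimated correlation). With no filter 6 of 31 members above 0 in any library rose and 0 fell, with a median of 0.27 (camera adjusted p = 0.00891). Ptgs2, the inducible prostaglandin synthase gene, went from 0.597 ± 0.115 to 15.9 ± 1.99 FPKM, and Fshr, the receptor for follicle stimulating hormone, from 0.158 ± 0.0183 to 10.6 ± 1.23 FPKM (SD, n = 3). Inhba was at 0.637 ± 0.324 and 2.75 ± 1.46 FPKM and lost its call without control replicate 1 or 2 (limma adjusted p up to 0.0842) and after the least-squares GC and length correction (0.0501). The most abundant members, Serpine2 and Esr2, were at 150 ± 14.2 and 163 ± 22.1 FPKM and at 19.6 ± 3.08 and 24.1 ± 0.727 FPKM, differences not past the threshold. Fewer than 5 members of the other 3 lists passed the filter, so camera was run on them only with no filter: 6 of 15 stroma and theca markers, 2 of 15 blood and immune markers and 1 of 11 endothelial markers rose and 0 fell (camera adjusted p = 0.00289, 0.132 and 0.214). Of 3 stroma and theca markers Fn1 and Nr2f2 rose (2 and 0 adjusted over the list alone), by 2.02 and 1.84 log2 units. Of 2 blood and immune markers C1qb rose (1 and 0 adjusted over the list alone), from 18.1 ± 2.10 to 48.7 ± 7.58 FPKM, and Cd68 was at 1.22 ± 0.767 and 1.75 ± 1.49 FPKM. Of 3 endothelial markers Flt1, which is also on the H3K27me3 imprinted list, rose and Pecam1 fell (1 and 1 adjusted over the list alone), by 1.59 and 0.72 log2 units, the latter not without control replicate 1 or 3 or dKO replicate 1 (limma adjusted p up to 0.130) or with array weights (0.0766).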

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

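The small RNA removal, the GC and length corrections, the centring of each library on its mean and the lists without shared members were chosen after seeing the data. The Rnf2 fall kept its direction and call in every setting run, and Ring1 was never past the threshold. No result reversed sign with a call, and the same holds for the 110 named genes past the threshold. Of these, 74 stayed past it whichever library was removed, and 36 (6 rising, 30 falling) lost their call on removal of at least 1. Of the 124 such losses, 77 went with a smaller log2 change and 47 with a larger one (0.704 to 1.18 times that with all libraries). Leaving out 1 library gave 1332 to 3031 changed genes, 1087 to 1869 rising, 231 to 1465 falling, 51.7% to 82.7% rising, and a difference in detected genes of 985 to 1249.

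The filter at 5 FPKM gave 1214 changed genes, 655 rising (54.0%), and left 0.0739% of genes with a mean under 3 FPKM rising because few such genes pass that filter. No filter gave 78.6% rising. Quantile normalization gave 52.6% rising, and 14.9% of genes with a mean under 3 FPKM rising. No filter ended 23 calls of named genes, quantile normalization 11, array weights 6, the filter at 5 FPKM 4, mean centring 3, pseudocounts of 0.1 and 0.5 3 and 2, eBayes without trend 2 and robust 1, the least-squares GC and length correction 2 (1 with the replicate block), and median-ratio scaling 1. A log2 change of at least 1 gave 1366 changed and 269 falling genes (80.3% rising), and an adjusted p under 0.1 gave 1390 falling. The replicate block gave 2568 changed genes. It ended the calls of Eed, Tdrkh, Wee2, Fen1 and Kdm1a, and changed no other call of a gene taken by the rule, list or overall result. Genes named after their values were seen are outside all counts of named genes in this section.

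The robust GC and length correction gave 1218 falling genes, and 1208 with the replicate block. By least squares, the version run before it, falls outnumbered rises: 2015 falling and 43.2% rising, and 1972 and 44.7% with the replicate block. Centring alone, with no trend removed, gave 1572 falling and 48.0% rising, so the construction of the least-squares version, which centres each library on its mean, gives most of that turn. The median of all genes then lay at -0.14 and -0.12. Camera with an estimated correlation called 4 lists in place of 11. Over all settings, list calls were gained 22 times and lost 18 times, each in the direction first found. Detected genes differed by 1496 at 0.1 FPKM and 388 at 5 FPKM. The cause of the other shifts was not tested. Absolute depth is unknown, which limits what can be said of genes near 0.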

Other observations

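The tests of the X chromosome and of the median over abundant granulosa transcripts were chosen only after the results were seen, as were the GC and length corrections, the centring of libraries and the scan of gene families with its permutations. Gene families, grouped by symbol stem, were scanned with Fisher's exact test in both directions (126 families of at least 10 tested genes, 252 tests, Benjamini-Hochberg adjusted; genes are not independent). Rising genes were enriched among keratins (Krt, 8 of 11, adjusted p = 0.00204), cadherins (Cdh, 7 of 11, 0.0172), Krüppel-like factors (Klf, 7 of 12, 0.0218), Zscan genes (7 of 13, 0.0297) and semaphorins (Sema, 6 of 10, 0.0298), against 14.0% of all tested genes. Falling genes were enriched among Fbxw genes (9 of 21, adjusted p = 0.00139) and Nlrp genes (5 of 13, 0.0382), against 7.04% of all. Rises were rare among histone genes (Hist, 0 of 56, adjusted p = 0.0214) and Rpl genes (0 of 50, 0.0297), though 1 histone gene rose after the robust GC and length correction. Of the histone genes 7 fell (adjusted p = 0.620), and 17 after quantile normalization, 16 after mean centring and 15 after the least-squares GC and length correction, while 2 Rpl genes fell, and 2, 4 and 6 in those settings. That scan was not matched on expression, so calls were permuted 1000 times within bins of mean expression, with no adjustment for the number of families: none gave as many rising Krt or falling Fbxw genes or as few rising histone genes, 1 as many rising Cdh, 2 Klf, 2 Zscan and 4 Sema genes, and 13 each as many falling Nlrp and falling histone genes. For Rpl genes 28 also gave 0 rises, with a permuted median of 3. These bins used the mean over all 6 libraries, so control level was not matched. Quantile normalization left 7 keratins, 4 cadherins, 5 Klf, 6 Zscan and 4 Sema genes rising and 8 Fbxw and 3 Nlrp genes falling. Reads can be split between members of the Krt, Zscan, Fbxw and Nlrp families.

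X-linked genes rose more often than others. Of 403 tested X-linked genes 109 rose, 27.1%, against at most 21.1% in 1000 permutations of the calls within bins of mean expression and 13.5% of autosomal genes (8.85% to 17.6% per chromosome). The X share lay above every permutation in each of the 22 other settings run (200 permutations each), at 18.1% to 31.5%. The settings with no filter and with the filter at 5 FPKM were not among them. The effect of the filter on this share was therefore not tested. The bins used the mean over all 6 libraries, so the permutations did not match genes on control level. Of tested genes with a control mean under 1 FPKM 77.4% rose. A larger share of such genes on the X could therefore give the same excess. The rising genes stood in 75 separate runs on the X. A class of X-linked genes more apt to rise in dKO oocytes may exist, as a hypothesis found and tested on the same data. The permutations cannot tell it apart from a difference in control level. The sequence at transcript starts was compared too: the median observed-to-expected CpG ratio over 300 bases was 0.735 in rising genes, above all 1000 sets of genes not past the threshold matched on expression (at most 0.726), and 0.615 in falling genes, below their lowest (0.704). The margin for rising genes is narrow. The bases were those of the longest annotated transcript, and the sets were not matched on GC content or on control level. Only calls without a GC correction were used, so a GC bias between libraries was not tested as a source of this difference.

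More genes rose than fell on the deposited scale, and the size of that excess stays open. A shift of the whole FPKM scale of the dKO libraries would drop the rising share by over 10 points after median-ratio scaling, and the share was 63.6% against 66.5%. That bound decides nothing, since the scaling factors averaged 1.02 ± 0.0185 in controls and 1.02 ± 0.0722 in dKO libraries (SD, n = 3) and so shifted neither group against the other, while centring on the mean, also 1 offset per library, gave 48.0% rising. A GC or length bias was held to a bound on rising genes, under 1058 of them. The bound was written before that test as a share of the main number, although the correction was added after the data were seen. The lower of both corrections left 1533 rising genes. Falls, which the bound did not cover, numbered 2015 by least squares and 1572 by mean centring alone. The median log2 change of all genes was -0.019 on the deposited scale and -0.12 after mean centring. More genes thus rose with the median gene near 0, and falls led once centring moved that gene below 0. The zero point of the libraries, not only a GC trend, may therefore set which direction is the more frequent. Of the 10 splits of the 6 libraries 1, the real one, gave as many changed genes (2385, highest other 2, and 1 among the 3 others that part all pairs), too few splits for a share under 0.05, and the library index, which differs between the groups throughout, cannot be told apart from genotype.

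Granulosa and cumulus markers were higher in dKO oocytes, which follicle cells left after the pipetting that removes them could produce. The test fixed beforehand asked how many of 12 abundant granulosa transcripts gained as much as the called markers (a median of 5.54 FPKM, within 2 SE), and 3 did, between the bounds set for and against carry-over, so it did not decide. The 3 were Fshr, itself a called marker, and Serpine2 and Nr5a2, already at 150 and 16.5 FPKM in controls. The median over all 12 of the gain plus 2 SE was 0.992 FPKM, below 5.54, and Cyp19a1 had a lower mean in dKO oocytes (5.78 against 9.94 FPKM), which argues against cells that bring all their abundant transcripts. A small carry-over, and a rise of single follicle genes within the oocyte, both stay open.

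Rising genes lay beside other rising genes. Of 1581 placed rising genes 39.2% had a rising nearest tested neighbour, against at most 31.1% in 1000 permutations within bins of mean expression, as regulation shared along the chromosome would give. Reads running over from an adjacent gene are argued against by the share with at least 1 annotated gene in between (39.5%, at most 30.5% permuted), and families sharing reads by the share with neighbours of another symbol stem (37.4%, at most 30.7%). The share was above every permutation in the same 22 other settings and for autosomes alone (38.5%, with 200 permutations each). The settings with no filter and with the filter at 5 FPKM were again not run. Of falling genes 19.25% had a falling nearest neighbour, near the highest permuted share of 19.5% (median 13.58%). With at least 1 annotated gene in between it was 16.73% (at most 19.25%). The longest run of rising genes, 7 genes, was below the longest permuted run of 9. The bins did not match control level, so neighbours that were both silent in controls could also raise the share of rising genes. Shared regulation of neighbouring genes may contribute, as a hypothesis found and tested on the same data.

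The rising genes rose by a median of 1.33, 1.28 and 1.22 log2 units in dKO replicates 1, 2 and 3, whose Rnf2 levels were 14.8, 8.44 and 5.31 FPKM, and no relation between them was tested.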
